A study of Mus musculus with 24 samples.

How the data were processed

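RNA from mouse prostate organoids and prostate tissue was sequenced, and 24 libraries were analysed. The 18 organoid libraries fall into 6 groups of 3 by genotype label (WT, HET or KO for Brca1) and by culture with or without dihydrotestosterone (DHT). The 6 tissue libraries fall into 3 groups of 2 by genotype label. All groups were taken from the sample titles and genotype labels. The series text calls the samples biological replicates without saying whether they came from separate animals or cultures, so the p-values measure only the spread between these samples.

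Each deposited file lists 116945 transcripts with estimated counts of reads, transcripts-per-million (TPM), lengths and effective lengths, per the file headers. The estimated counts and TPM were made with Salmon 0.13.1, per the submitters' processing notes. These notes also name the genome build hg38, whereas the transcript identifiers in the deposited files are mouse Ensembl identifiers. The values were therefore read as mouse, and the annotation behind the Salmon index is not given in the sources used here. Read trimming, library strandedness and Salmon settings are likewise not given in the sources used here. Without strand information, reads from a gene and an overlapping antisense gene cannot be told apart.

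Estimated counts were summed per gene with the transcript-to-gene map of GENCODE mouse release 21 and rounded to whole numbers. In each library 1000 transcripts had no gene in that map. They held between 0.241% and 0.348% of the estimated reads and were left out. Library totals ranged from 11965815 to 58445041 estimated reads. Counts-per-million (CPM) were computed with library sizes scaled by the trimmed mean of M-values (TMM).

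Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold and no threshold on the fold change. Low-count genes were removed with the filterByExpr function by group. The 18 organoid libraries were fitted together, with 1 mean per group, 15415 genes and 12 residual degrees of freedom. The 6 tissue libraries were fitted separately, with 16739 genes and 3 residual degrees of freedom. The biological coefficient of variation was 0.214 in organoids and 0.501 in tissue. In organoids 12 comparisons were made. They were DHT withdrawal within each genotype label, the 3 differences between these withdrawal responses, and the 3 pairwise genotype comparisons in each medium. In tissue the 3 pairwise genotype comparisons were made. Standard errors of log2 changes are those of the edgeR fit.

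Before the data were examined, 28 gene lists were fixed: hormone response, epithelial cell types, pathways, and markers of other cell types that prostate tissue or cultures could hold. List members were matched by symbol, or by an older symbol for Ankh, Acp3 and Ero1a. Trop2, Loricrin, Aoc1l3 and Semg1 were not matched, and Troy was dropped because it is a synonym of Tnfrsf19. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over all lists and comparisons of the same material. Camera with a correlation estimated per list, and fry, were run as alternatives. For each list the members past the threshold were counted, both adjusted over all genes and adjusted over the list alone.

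The rule for naming genes was also fixed beforehand. It takes Brca1 and the tested steroid receptors in every comparison. It adds the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in a compared group and no overlap between the samples compared. This was 5 and 5 for comparisons of KO with HET and for differences between withdrawal responses, the latter without the demand for no overlap. Symbols that start with Gm and a digit, end in Rik or look like clone identifiers were left out of this part. From each list described, it takes up to 4 called members with the lowest p, or the 2 members with the highest CPM where none was called. Genes named outside this rule are said to have been chosen after their values were seen.

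Alternatives fixed beforehand for the gene tests were DESeq2 1.42.0, its size factors within edgeR, no low-count filter, a stricter filter of over 1 CPM, offsets for transcript length, the replicate number as a block, fits restricted to the groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data left out the 3 organoid libraries with the fewest reads, the 3 that stood apart in principal components, or tissue libraries WT 2 and HET 1, kept only protein-coding genes, or added the mitochondrial read share as a covariate.

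The test was checked on counts drawn from each gene's mean over all libraries of the material, with the real library sizes and dispersions and 200 genes changed. For DHT withdrawal in WT organoids, over 15188 genes, it recovered 19.7%, 50% and 81.5% of genes changed 1.5-fold, 2-fold and 4-fold. For HET against WT with DHT, over 15208 genes, these shares were 16.7%, 54.5% and 83.1%. For the difference between the HET and WT withdrawal responses, over 15199 genes, they were 1.52%, 34.8% and 70.8%. For HET against WT tissue, over 16429 genes, none of the changed genes was recovered at any of these sizes. In the same order, 9, 9, 5 and 0 unchanged genes were called. Genes were drawn independently, so the check holds no structure shared between samples.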

Results

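Prostate organoids were grown in Matrigel from anterior lobes of mice carrying wild-type (WT), heterozygous (HET) or homozygous knockout (KO) labels for Brca1, a gene of homologous recombination repair. They were cultured with or without dihydrotestosterone (DHT), a potent androgen, and anterior lobe tissue of the same genotype labels was sequenced directly. The comparisons address how loss of Brca1 from 1 or both chromosomes bears on the response to androgen withdrawal. The 24 libraries held 11965815 to 58445041 estimated reads. The smallest was WT plus DHT replicate 1, in which Lars2 took 28.1% of reads, and the next smallest held 25233980. Mitochondrial genes took 9.43%, 4.54% and 2.42% of reads in the 3 HET minus DHT libraries and 10.01%, 4.17% and 2.61% in the 3 KO minus DHT libraries. Correlations between replicates across genes ranged from 0.9517 to 0.989 in organoids and from 0.875 to 0.967 in tissue.

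Brca1 RNA did not follow the genotype labels. With DHT, Brca1 averaged 13.7 counts-per-million (CPM; SD 0.557, n = 3) in WT, 16.8 (SD 1.85, n = 3) in HET and 10.9 (SD 1.11, n = 3) in KO organoids. Without DHT it averaged 12.9 (SD 1.53), 18.7 (SD 1.56) and 11.4 (SD 1.47) CPM, with 3 libraries each. Brca1 was higher in HET than in WT organoids without DHT, by a log2 change of 0.53 (SE 0.127, adjusted p = 0.0147 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while with DHT the change was 0.30 (SE 0.128, edgeR adjusted p = 0.211). It was lower in KO than in HET organoids with DHT (log2 -0.63, SE 0.127, edgeR adjusted p = 0.0101) and without it (log2 -0.71, SE 0.128, edgeR adjusted p = 0.00539). Against WT, the KO change was -0.34 with DHT (SE 0.129, edgeR adjusted p = 0.221) and -0.18 without (SE 0.127, edgeR adjusted p = 0.596). Tissue held 3.1 and 4.16 CPM in WT, 3.03 and 3.27 in HET and 2.2 and 3.78 in KO. The deleted part of the gene is not given, and a transcript lacking some exons can still be counted, so RNA level cannot fully check the labels. Groups are therefore called HET-labelled and KO-labelled, and each direction below rests on those labels.

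**Figure D1:**
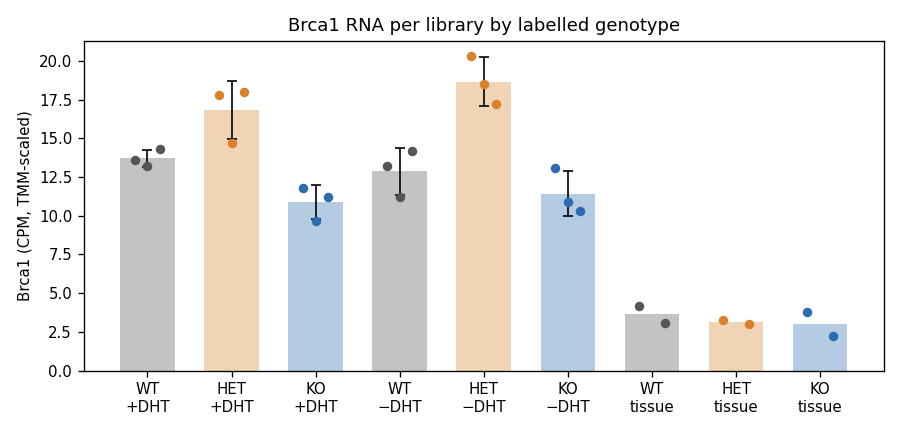
Brca1 in counts-per-million on the vertical axis for each library, grouped by material, medium and genotype label; bars are group means and error bars are SD for groups of 3 libraries. Brca1 is highest in HET-labelled organoids and is still detected in all KO-labelled libraries.

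Removal of DHT lowered known androgen-induced genes in organoids of all 3 genotype labels. Fkbp5, a co-chaperone of steroid receptors, fell from 67 CPM (SD 9.98) to 18.9 CPM (SD 0.723) in WT organoids, with 3 libraries each. Its log2 change was -1.83 in WT (SE 0.148, edgeR adjusted p = 1.2e-05), -1.42 in HET-labelled (SE 0.147, edgeR adjusted p = 0.000108) and -1.45 in KO-labelled organoids (SE 0.147, edgeR adjusted p = 0.000107). Among genes eligible under the naming rule, with a group mean of at least 5 CPM and no overlap between samples, the largest falls in WT were Aldh1a7 (log2 -2.58, SE 0.295), the proton pump subunit Atp12a (log2 -2.25, SE 0.237) and the retinaldehyde dehydrogenase Aldh1a1 (log2 -2.21, SE 0.213). All 3 fell in the other genotypes as well, with log2 changes of -2.52, -1.95 and -2.26 in HET-labelled and -2.73, -2.20 and -2.07 in KO-labelled organoids.

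The imprinted gene Peg10 showed the largest rise among such genes in each genotype, with log2 changes of 4.32 in WT (SE 0.326, edgeR adjusted p = 6.67e-06), 2.92 in HET-labelled (SE 0.272, edgeR adjusted p = 6.05e-05) and 2.97 in KO-labelled organoids (SE 0.268, edgeR adjusted p = 4.97e-05). In WT it went from 0.238 to 5.54 CPM. The antimicrobial lectin Reg3g rose by log2 1.97 in WT, 1.15 in HET-labelled and 1.39 in KO-labelled organoids, and the growth arrest gene Gas1 by 1.83, 1.38 and 1.36. The matrix gene Thbs2 rose by 1.76, 1.53 and 1.34. Of the steroid receptors, Esr1 rose in WT (log2 0.52, SE 0.106, edgeR adjusted p = 0.0204), with 0.39 (adjusted p = 0.149) and 0.32 (adjusted p = 0.327) in HET-labelled and KO-labelled organoids. Nr3c1, the glucocorticoid receptor, changed by 0.30, 0.13 and 0.01 (edgeR adjusted p = 0.71, 0.9 and 1). Pgr was too low to be tested in organoids.

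**Figure D2:**
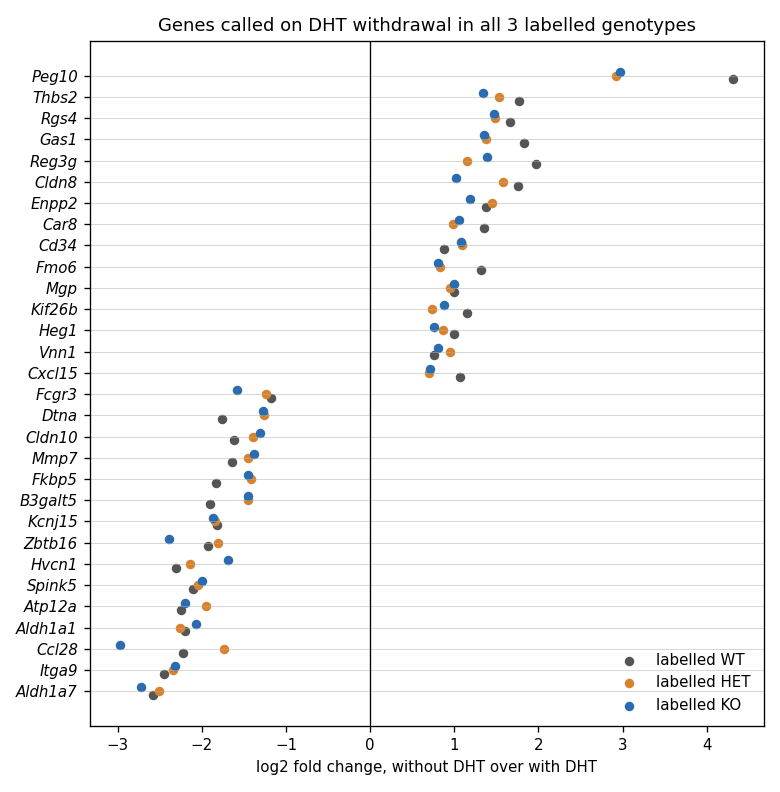
Log2 change on DHT withdrawal (horizontal axis) for 15 rising and 15 falling genes that passed the edgeR test in all 3 genotype labels, with 1 point per genotype. Points of the 3 genotypes lie on the same side of 0 for each gene.

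Androgen-dependent prostate secretory genes fell on withdrawal. Of 12 measured members, 5 fell in WT, 3 in HET-labelled and 3 in KO-labelled organoids, and none rose. Adjusted over the list alone, 7, 6 and 7 fell and 1 rose in each. Camera placed the list below other genes in all 3 (adjusted p = 7.89e-08, 2.48e-07 and 5.04e-12, and adjusted p = 0.0192, 0.0221 and 0.00834 with an estimated correlation). In the WT organoids Fkbp5, the protease inhibitor Spink5 (log2 -2.10) and the membrane endopeptidase Mme (log2 -2.01) fell. Among 79 androgen response genes, 7, 4 and 6 fell and none rose, and 9, 11 and 12 fell with 3, 2 and 1 rising when adjusted over the list alone. That list was placed lower (camera adjusted p = 3.2e-04, 0.0324 and 1.3e-04), and the call was lost at adjusted p = 0.109, 0.317 and 0.0902 with an estimated correlation. Glucocorticoid receptor targets, 20 measured, share Fkbp5 and Zbtb16 with the androgen list. Of these 4 fell in WT, 2 in HET-labelled and 3 in KO-labelled organoids, and 7, 5 and 4 fell with 1, 0 and 0 rising when adjusted over the list alone (camera adjusted p = 1.43e-04, 5.44e-09 and 1.58e-08, and adjusted p = 0.0876, 0.0182 and 0.0192 with an estimated correlation).

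Wnt targets went up on withdrawal. Of 13 measured members, 2 rose in WT, 2 in HET-labelled and 1 in KO-labelled organoids, none fell, and 3, 2 and 2 rose when adjusted over the list alone (camera adjusted p = 2.74e-04, 0.00184 and 0.00137, and adjusted p = 0.0192, 0.0338 and 0.0311 with an estimated correlation). Apcdd1, a Wnt antagonist, rose by log2 0.81 (SE 0.104), 0.56 (SE 0.104) and 0.49 (SE 0.103). Lgr5, a stem cell receptor for R-spondin, rose from 0.111 to 0.757 CPM in WT and from 0.0566 to 0.395 CPM in HET-labelled organoids (edgeR adjusted p = 0.00258 and 0.00757). Members of the luminal progenitor list went both ways in WT, where Psca (log2 -1.27), Cldn10 (log2 -1.62) and Lcn2 (log2 -0.73) fell and Clu (log2 0.68) rose. Of its 15 members, 4 fell and 1 rose in WT, while Cldn10 alone passed in HET-labelled and KO-labelled organoids. Adjusted over the list alone, 4, 4 and 5 fell and 1, 0 and 0 rose (camera adjusted p = 7.27e-04, 0.00298 and 0.0243, lost at adjusted p = 0.403, 0.45 and 0.562 with an estimated correlation). Mesenchymal transition genes, 14 measured, held 1, 2 and 1 rising members, among them Sparc in WT (log2 0.44), Mmp3 in HET-labelled (log2 1.22) and Tnc in KO-labelled organoids (log2 0.55). Adjusted over the list alone, 3 rose in each and 0, 1 and 1 fell (camera adjusted p = 0.0133, 0.0087 and 0.00244, lost at adjusted p = 0.122, 0.109 and 0.0659 with an estimated correlation).

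Several other lists shifted on withdrawal with no more than 2 members past the gene test, and all of their calls were lost with an estimated correlation. Unfolded protein response genes were lower in all 3 genotypes (camera adjusted p = 0.00803, 8.67e-04 and 0.00311, and adjusted p = 0.282, 0.178 and 0.233 with an estimated correlation). Hypoxia and glycolysis genes were higher in WT (0.0166, estimated correlation adjusted p = 0.514) and lower in HET-labelled (7.68e-06, estimated correlation adjusted p = 0.237) and KO-labelled organoids (9.89e-05, estimated correlation adjusted p = 0.294). In WT, type I interferon genes (camera adjusted p = 5.91e-07, and adjusted p = 0.344 with an estimated correlation), squamous genes (2.54e-04 and 0.0723), cell cycle genes (0.00205 and 0.275) and homologous recombination genes (0.0428 and 0.438) were lower, and p53 targets were higher (0.00267 and 0.294). Cell cycle genes were higher in KO-labelled organoids (0.00244 and 0.282), although the ribonucleotide reductase gene Rrm2 fell. MAPK output genes were higher in HET-labelled (0.015 and 0.294) and KO-labelled organoids (2.03e-04 and 0.122), and cholesterol synthesis genes were lower in both (0.0143 and 0.416, then 0.0309 and 0.461).

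Withdrawal changed 200 of 15415 genes in WT (93 up, 107 down), 109 in HET-labelled (53 up, 56 down) and 86 in KO-labelled organoids (30 up, 56 down). Of these, 23 rose and 33 fell in all 3. HET-labelled and WT organoids shared 37 rising and 44 falling genes where independent calls would share 0.32 and 0.39, and no gene was called in opposite directions in any pair. Across all 15415 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.155 for HET-labelled and WT, 0.146 for KO-labelled and WT and 0.313 for KO-labelled and HET-labelled organoids (Spearman 0.235, 0.306 and 0.466). The stricter low-count filter gave 0.272, 0.216 and 0.446, and over genes called in either of a pair, which were picked for their change, r was 0.89, 0.861 and 0.949. With DESeq2 the counts were 396, 290 and 274, with the mitochondrial read share as a covariate 715, 293 and 452, and without the 3 libraries with the fewest reads 332 in WT. Leaving out single libraries gave 116 to 196, 43 to 81 and 42 to 59 genes, lowest without WT plus DHT 3, HET plus DHT 2 and KO plus DHT 2, and a fit restricted to the 6 libraries compared gave 94, 0 and 12.

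The withdrawal response itself was then compared between genotypes. No single gene passed the edgeR test of this difference for HET-labelled against WT, KO-labelled against WT or KO-labelled against HET-labelled organoids. At unadjusted p < 0.05 there were 433, 418 and 151 genes where 771 would be expected by chance, and DESeq2 called 4, 5 and 1. Each of these sets held a call with an extreme log2 difference, in genes named after their values were seen. These were Gm10273 (-48.77), 1700047I17Rik2 (-48.723) and, as the only call for KO-labelled against HET-labelled organoids, Gm10273 (47.82). In edgeR they stood at -21.221, -21.335 and 19.872 and did not pass. The matrix gene Smoc2, chosen after its values were seen, was in the first 2 of these DESeq2 sets, with log2 differences of -1.30 (DESeq2 adjusted p = 0.00352) and -1.41 (DESeq2 adjusted p = 0.000143), and in edgeR -1.33 (adjusted p = 0.515) and -1.43 (adjusted p = 0.2). It rose in WT on withdrawal by log2 1.38 (SE 0.161). Gene lists did differ. Cell cycle genes responded more positively in KO-labelled than in WT organoids, with 36 of 38 members above 0 and a median difference of 0.22 (camera adjusted p = 1.75e-09, and adjusted p = 0.0367 with an estimated correlation). Squamous genes did so in HET-labelled organoids, with 18 of 19 members above 0 and a median of 0.38 (camera adjusted p = 5.17e-05, and adjusted p = 0.0487 with an estimated correlation), and in KO-labelled organoids, with 16 of 19 and a median of 0.25 (camera adjusted p = 7.68e-06, and adjusted p = 0.0338 with an estimated correlation). No list differed between KO-labelled and HET-labelled responses. A difference that misses the threshold does not show that the genotypes responded alike.

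HET-labelled organoids carried more RNA of cell cycle genes than WT organoids in both media. The mitotic kinase gene Aurka averaged 37.8 CPM (SD 0.23, n = 3) against 22.2 CPM (SD 2.3, n = 3) with DHT (log2 0.76, SE 0.0826, edgeR adjusted p = 2.64e-05), and 40 CPM (SD 1.06) against 21.1 CPM (SD 1.28) without (log2 0.92, SE 0.082, edgeR adjusted p = 3.33e-06). Of 38 cell cycle genes, 24 rose with DHT and 31 without, none fell, and 32 and 34 rose when adjusted over the list alone (camera adjusted p = 1.61e-23 and 6.1e-34, and adjusted p = 0.00584 and 0.00211 with an estimated correlation). With the mitochondrial read share as a covariate, the call with DHT was lost with an estimated correlation (camera adjusted p = 0.0596). Bub1b (log2 0.60), Kif20a (log2 0.64) and Ccnb1 (log2 0.74) followed Aurka with DHT, and Kif20a (log2 0.85), Plk1 (log2 0.89) and Ccnb2 (log2 0.84) without. Homologous recombination genes rose with them, 9 of 30 with DHT and 15 without, and 14 and 20 rose with 0 and 1 falling when adjusted over the list alone. Rad54b (log2 0.94, SE 0.142) and Rad51ap1 (log2 0.89) rose with DHT, and Rad51ap1 (log2 1.10) and Rad54b (log2 0.97, SE 0.139) without (camera adjusted p = 3.46e-07 and 1.46e-12, and adjusted p = 0.0659 and 0.0192 with an estimated correlation).

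Basal epithelial and Wnt target genes were lower in HET-labelled than in WT organoids. Of 20 basal genes, 7 fell with DHT and 5 without, none rose, and 7 and 6 fell when adjusted over the list alone (camera adjusted p = 5.91e-07 and 3.79e-06, and adjusted p = 0.0221 and 0.0311 with an estimated correlation). The desmosomal cadherins led, with Dsg3 at log2 -1.23 (SE 0.117) and Dsc3 at -1.45 (SE 0.143) with DHT, and Dsc3 at -1.62 and Dsg3 at -0.81 without. Of 13 Wnt targets, 3 fell with DHT and 4 without, none rose, and 6 and 5 fell when adjusted over the list alone (camera adjusted p = 1.35e-05 and 2.96e-06, and adjusted p = 0.0108 and 0.00834 with an estimated correlation). Apcdd1 fell by log2 -1.06 (SE 0.106) and -1.30 (SE 0.104), and the feedback inhibitor Axin2, which lies within 20 Mb of Brca1, by -1.22 (SE 0.13) and -1.08 (SE 0.129). Squamous genes were lower with DHT, where 5 of 19 fell, 7 when adjusted over the list alone, led by the stress keratin Krt16, also within 20 Mb of Brca1 (log2 -1.14, SE 0.147), and the cornified envelope gene Sprr2h (log2 -1.19; camera adjusted p = 2.13e-06, and adjusted p = 0.0275 with an estimated correlation). Without DHT Krt16 fell (log2 -0.99) while Sprr1a rose (log2 0.69), and the list was not called (camera adjusted p = 0.0617).

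**Figure D3:**
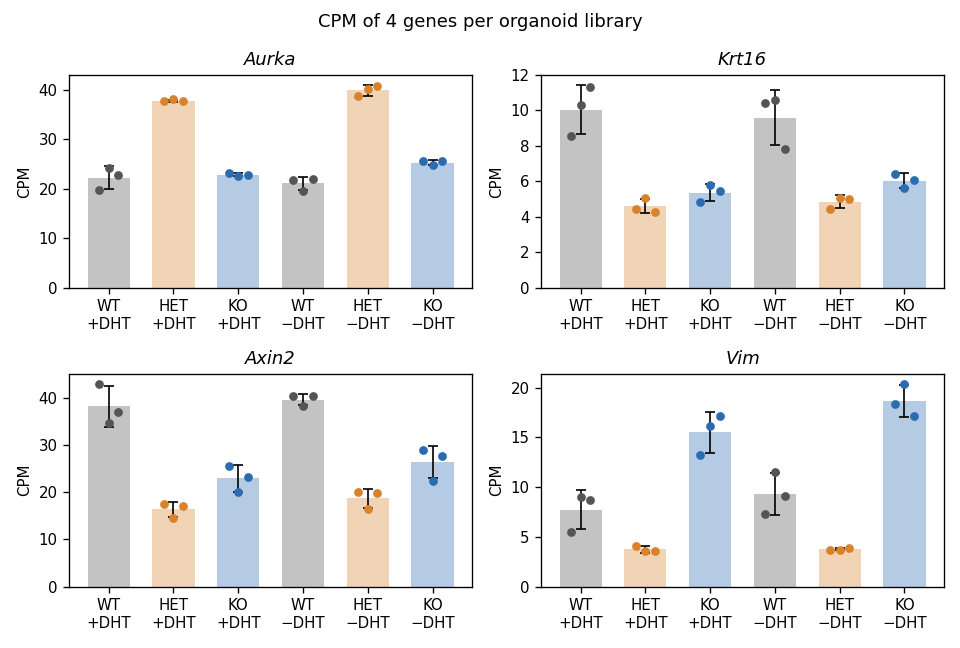
Counts-per-million (vertical axes) of Aurka, Krt16, Axin2 and Vim in each organoid library by genotype label and medium; bars are means of 3 libraries and error bars are SD. Aurka is highest and Axin2 and Vim are lowest in HET-labelled organoids.

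Mesenchymal transition genes went both ways in HET-labelled organoids. Sparc fell by log2 -2.00 with DHT (SE 0.0932, edgeR adjusted p = 3.32e-09) and -2.07 without, Vim by -1.08 and -1.30 and Tnc by -0.76 and -0.60, while the fibronectin gene Fn1 rose by 1.10 (SE 0.149) and 0.76. With DHT 2 of 14 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0199, lost at adjusted p = 0.143 with an estimated correlation), and without DHT 1 rose and 3 fell (camera adjusted p = 0.0981). Cholesterol synthesis genes were lower, with 4 and 5 of 25 falling, 5 and 5 when adjusted over the list alone (camera adjusted p = 0.00107 and 4.89e-05, lost at adjusted p = 0.282 and 0.183 with an estimated correlation). Hsd17b7 fell by log2 -0.91 and -0.77. Of 25 unfolded protein response genes 3 rose in each medium, 5 and 4 when adjusted over the list alone, among them the stress transcription factor gene Ddit3 (log2 1.22 with DHT and 0.71 without; camera adjusted p = 9.34e-04 and 0.00458, lost at adjusted p = 0.18 and 0.251 with an estimated correlation). Hypoxia and glycolysis genes were higher with DHT, where 4 of 25 rose, 5 when adjusted over the list alone, led by Pfkfb3 (log2 0.97; camera adjusted p = 0.00272, lost at adjusted p = 0.429 with an estimated correlation). Interferon genes split, with 3 rising and 3 falling with DHT and 5 rising and 1 falling without (camera adjusted p = 0.721 and 0.339).

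The androgen response list was not shifted between HET-labelled and WT organoids (camera adjusted p = 0.822 and 0.691), with 6 members rising and 9 falling with DHT and 7 and 5 without. Srd5a1, the steroid 5-alpha-reductase that makes DHT from testosterone, rose from 24.2 CPM (SD 4.02) to 73.1 CPM (SD 0.979) with DHT (log2 1.58, SE 0.119, edgeR adjusted p = 6.17e-07) and by log2 1.44 without (SE 0.117, edgeR adjusted p = 1.54e-06). The mineralocorticoid receptor gene Nr3c2 rose by 1.03 and 0.85. Nr3c1 differed by 0.27 and 0.10 and Esr1 by -0.05 and -0.18, and neither passed. Among the largest differences were genes that were nearly silent in WT. Rpl34-ps1 had 189 CPM in HET-labelled and 0.0297 CPM in WT organoids with DHT (edgeR adjusted p = 3.57e-12), the meiotic cohesin gene Rec8 8.67 and 0.0297 CPM (3.18e-08), the proteoglycan gene Spock1 39.8 and 0.253 CPM (5.1e-10) and Eno1b 618 and 5.2 CPM (2.18e-06). Rpl34-ps1 and Eno1b are near copies of other genes and can take reads from them, and Eno1 itself fell in HET-labelled organoids without DHT (log2 -0.75, edgeR adjusted p = 0.0466). Sptssb (log2 -4.45, SE 0.51) and the clock-related gene Arntl2 (log2 -2.99, SE 0.245) were among the largest falls with DHT.

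In total 1153 genes differed between HET-labelled and WT organoids with DHT (619 up, 534 down) and 1203 without (696 up, 507 down), and 769 of them did so in both media in the same direction (452 up, 317 down). Leaving out single libraries gave 707 to 838 genes with DHT, lowest without HET plus DHT 3, and 808 to 1474 without DHT. A fit restricted to the libraries compared gave 389 without DHT, and the mitochondrial read share as a covariate gave 2722 and 2275.

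KO-labelled organoids had lower RNA of cholesterol synthesis genes than WT organoids. All 25 members were below 0 in both media. With DHT 4 fell and without it 6, none rose, and 9 and 12 fell when adjusted over the list alone (camera adjusted p = 1.75e-09 and 1.36e-09, and adjusted p = 0.0487 and 0.0481 with an estimated correlation). Acat2 (log2 -0.73, SE 0.113, edgeR adjusted p = 0.00085) and Dhcr7 (log2 -1.05) fell with DHT, and Stard4 (log2 -0.55), the squalene epoxidase gene Sqle (log2 -0.49, SE 0.098, edgeR adjusted p = 0.007) and Dhcr7 (log2 -1.16) without. Wnt targets were lower too, 2 of 13 with DHT and 4 without, 3 and 4 when adjusted over the list alone (camera adjusted p = 0.00111 and 9.38e-05, and adjusted p = 0.0301 and 0.0161 with an estimated correlation). Axin2 fell by log2 -0.73 (SE 0.129) with DHT and -0.59 without, and Apcdd1 by -0.52 (SE 0.104) and -0.84 (SE 0.103). Squamous genes were lower with DHT, where 3 of 19 fell, 10 when adjusted over the list alone, with Krt16 at log2 -0.92 (SE 0.146) and Krt13 at -0.70 (camera adjusted p = 2.35e-05, and adjusted p = 0.042 with an estimated correlation). Without DHT 1 rose and 1 fell (camera adjusted p = 0.449).

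Fibronectin and contractile genes were higher in KO-labelled organoids. Fn1 rose by log2 2.01 with DHT (SE 0.152, edgeR adjusted p = 6.67e-07) and 1.78 without (SE 0.15, edgeR adjusted p = 2.4e-06), and Vim by 0.97 (SE 0.183) and 1.01 (SE 0.18). Of 14 mesenchymal genes 2 rose with DHT and 3 without, 6 and 3 rose with 1 and 0 falling when adjusted over the list alone (camera adjusted p = 0.0263 and 0.0189, lost at adjusted p = 0.163 and 0.143 with an estimated correlation). Of 8 smooth muscle genes 3 rose with DHT and 2 without, the same numbers as when adjusted over the list alone (camera adjusted p = 0.00128 and 2.56e-04, and adjusted p = 0.0659 and 0.0402 with an estimated correlation). Their levels were low, with smooth muscle actin Acta2 at 3.2 CPM in KO-labelled and 0.558 CPM in WT organoids with DHT (log2 2.46, SE 0.404) and Tagln at 1.9 and 0.258 CPM (log2 2.68, SE 0.402). Type I interferon genes were lower, with 5 of 32 falling with DHT, and 5 falling and 1 rising without, 9 and 5 falling when adjusted over the list alone. The antiviral GTPase gene Mx2 fell by log2 -1.02 and -1.20 (camera adjusted p = 2.46e-06 and 0.0397, lost at adjusted p = 0.378 and 0.715 with an estimated correlation).

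Among DNA repair genes, the checkpoint kinase gene Chek2 rose in KO-labelled organoids by log2 0.79 with DHT (SE 0.107, edgeR adjusted p = 0.000237) and 0.81 without (SE 0.106, edgeR adjusted p = 0.000178). The homologous recombination list was called without DHT, with 2 of 30 rising, 3 when adjusted over the list alone (camera adjusted p = 3.68e-04, lost at adjusted p = 0.191 with an estimated correlation), and not with DHT (camera adjusted p = 0.0956). Cell cycle genes were higher without DHT, where 2 of 38 rose, 12 when adjusted over the list alone, among them Kif20a (log2 0.39; camera adjusted p = 3.88e-07, lost at adjusted p = 0.0716 with an estimated correlation). Of 28 p53 targets 2 rose with DHT, Zfp365 (log2 1.65) and the death receptor gene Fas (log2 0.74), 6 when adjusted over the list alone (camera adjusted p = 1.28e-04, lost at adjusted p = 0.183 with an estimated correlation). Hypoxia and glycolysis genes were lower without DHT, where 5 of 25 fell, 9 when adjusted over the list alone, led by the glucose transporter gene Slc2a1 (log2 -0.59; camera adjusted p = 1.98e-07, lost at adjusted p = 0.164 with an estimated correlation). Unfolded protein response genes were lower in both media with 1 and 2 of 25 falling, 1 and 3 when adjusted over the list alone, Herpud1 by log2 -0.47 and -0.60 (camera adjusted p = 2.89e-04 and 8.11e-04, lost at adjusted p = 0.143 and 0.177 with an estimated correlation).

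Srd5a1 rose in KO-labelled organoids by log2 1.65 (SE 0.119, edgeR adjusted p = 3.82e-07) with DHT and 1.68 (SE 0.118, edgeR adjusted p = 2.43e-07) without. Nr3c1 differed by 0.31 and 0.03 and Esr1 by 0.32 and 0.13, and neither passed. Rpl34-ps1 (155 CPM), Spock1 (50.9 CPM) and Rec8 (7.28 CPM) were again far above their WT levels with DHT. Ferritin pseudogenes were near 0, with Ftl2-ps at 0 CPM in KO-labelled and 123 CPM in WT organoids with DHT (edgeR adjusted p = 2.77e-09), Ftl1-ps2 at 0.086 and 20.2 CPM and Ftl1-ps1 at 3.04 and 455 CPM, and such copies share reads with their parent genes. The Fc receptor gene Fcgr3 had 0.481 and 20.1 CPM (edgeR adjusted p = 2.53e-10), and the nuclear import gene Kpna2, which lies within 20 Mb of Brca1, fell by log2 -4.39 (SE 0.171, edgeR adjusted p = 2.1e-10) with DHT and -3.88 without. In total 635 genes differed with DHT (390 up, 245 down) and 742 without (436 up, 306 down), and 431 did so in both media in the same direction (271 up, 160 down). Single libraries left out gave 395 to 562 and 412 to 732 genes, lowest without WT plus DHT 3 and WT minus DHT 1, and DESeq2 gave 967 and 1152. A fit restricted to the libraries compared gave 201 without DHT, and the mitochondrial read share as a covariate gave 1374 and 1656.

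Set directly against HET-labelled organoids, KO-labelled organoids had less RNA of cell cycle and unfolded protein response genes and more of mesenchymal and basal genes. Of 38 cell cycle genes 20 fell with DHT and 18 without, 32 and 31 when adjusted over the list alone (camera adjusted p = 5.93e-31 and 8.98e-33, and adjusted p = 0.00211 in both with an estimated correlation). Aurka fell by log2 -0.73 (SE 0.0818, edgeR adjusted p = 8.38e-05) and -0.66 (SE 0.0818, edgeR adjusted p = 0.000254). Of 25 unfolded protein response genes 10 and 5 fell, 15 and 14 when adjusted over the list alone, among them Asns (log2 -0.79 and -0.69) and Ddit3 (log2 -1.08 and -1.03; camera adjusted p = 1.65e-13 and 3.21e-14, and adjusted p = 0.0108 in both with an estimated correlation). Mesenchymal genes rose, 4 of 14 in each medium, 5 and 5 with 0 and 1 falling when adjusted over the list alone (camera adjusted p = 3.22e-06 and 3.72e-06, and adjusted p = 0.0148 in both with an estimated correlation). Sparc rose by log2 2.26 (SE 0.0937, edgeR adjusted p = 6.58e-10) and 2.23, and Vim by 2.06 (SE 0.188, edgeR adjusted p = 8.68e-06) and 2.31 (SE 0.19, edgeR adjusted p = 2.63e-06). Markers of other cell types rose with them, among them the fibroblast marker Dcn (log2 1.69 and 1.39), Ncam1 (log2 1.82 and 2.03) and the smooth muscle genes Acta2 (log2 1.90 and 2.04) and Tagln (log2 1.53 and 1.53). Of 20 basal genes 4 and 3 rose, 6 and 7 when adjusted over the list alone, with Dsc3 at log2 1.25 and 1.12 and Pdpn at 0.79 and 0.82 (camera adjusted p = 1.35e-05 and 2.94e-07, and adjusted p = 0.0384 and 0.0192 with an estimated correlation).

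Homologous recombination genes were lower in KO-labelled than in HET-labelled organoids, 3 of 30 with DHT and 7 without, with 9 and 11 falling and 1 and 0 rising when adjusted over the list alone (camera adjusted p = 1.99e-05 and 3.58e-08, and adjusted p = 0.122 and 0.0474 with an estimated correlation). Rad51ap1 fell by log2 -0.82 with DHT, and Rad54l by -0.81 and Rad51ap1 by -0.72 without. Interferon genes were lower, with 2 and 1 of 32 falling, 5 and 1 when adjusted over the list alone, and the oligoadenylate synthetase gene Oas2 at log2 -1.22 and -1.26 (camera adjusted p = 2.56e-05 and 9.34e-06, lost at adjusted p = 0.435 and 0.413 with an estimated correlation), as were hypoxia genes, with 3 and 1 of 25 falling (camera adjusted p = 1.99e-05 and 1.05e-04, lost at adjusted p = 0.262 and 0.294 with an estimated correlation). In the comparison with DHT, Wnt targets (camera adjusted p = 0.0306, lost at adjusted p = 0.112 with an estimated correlation) and cholesterol synthesis genes (0.0467, lost at adjusted p = 0.497 with an estimated correlation) were higher. In the comparison without DHT, p53 targets (0.0121, lost at adjusted p = 0.378 with an estimated correlation) and smooth muscle genes (0.0282, lost at adjusted p = 0.183 with an estimated correlation) were higher and prostate secretory genes were lower (0.00569, lost at adjusted p = 0.183 with an estimated correlation), the latter with falls of Pigr (log2 -0.63) and Cd177 (log2 -1.29). Xlr3b had 13.5 CPM in HET-labelled and 0.0511 CPM in KO-labelled organoids with DHT (edgeR adjusted p = 2.49e-07).

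In total 544 genes differed between KO-labelled and HET-labelled organoids with DHT (276 up, 268 down) and 448 without (208 up, 240 down). Single libraries left out gave 246 to 351 and 226 to 366 genes, lowest without KO plus DHT 1 and KO minus DHT 2, and DESeq2 gave 976 and 786. A fit restricted to the libraries compared gave 1234 and 27, length offsets gave 273 without DHT, leaving out the 3 libraries that stood apart in principal components gave 254 without DHT, and the mitochondrial read share as a covariate gave 1579 and 1312.

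Apart from the smooth muscle list, called higher in KO-labelled organoids as given above, markers of other cell types moved with genotype in a few single genes. The proteoglycan gene Dcn, a fibroblast marker, was lower in HET-labelled than in WT organoids (log2 -1.23 with DHT and -1.77 without), as was the adhesion gene Ncam1 (log2 -1.38 and -2.53). The class II gene H2-Ab1 was higher in HET-labelled (log2 1.26 and 1.29) and KO-labelled organoids (log2 1.52 and 1.76), as was the myoglobin gene Mb (log2 1.14 and 1.26, then 0.90 and 0.88). The lists of these types were not called in any of the 12 organoid comparisons, with smallest camera adjusted p = 0.0792 for fibroblast (7 members measured), 0.29 for leukocyte (7), 0.185 for endothelial (4), 0.0886 for adipocyte (5), 0.0507 for neuroendocrine (6), 0.0831 for seminal vesicle (2) and 0.114 for skeletal muscle markers (4). The same held for NF-kappaB genes (0.134, 25 measured), luminal epithelial genes (0.104, 16 measured) and the list of steroid receptors and androgen metabolism (0.05, 14 measured).

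In tissue, 2 of 6 libraries differed from the others in secretory transcripts. Svs2, a seminal vesicle secretory gene, had 146000 CPM in WT replicate 2 and 33900 CPM in HET-labelled replicate 1, and between 0.44 and 3.93 CPM in the other 4 libraries. Tgm4, a secreted prostate transglutaminase, had 38900 CPM in WT replicate 2, 1.38 CPM in HET-labelled replicate 1 and 901 to 2930 CPM in the others. Pigr, which carries immunoglobulin across epithelia, had 64.9 CPM in WT replicate 2 and 7710 to 11300 CPM in the others. Further genes, chosen after their values were seen, followed these libraries. Pbsn, an androgen-dependent prostate gene, had 13300 CPM in WT replicate 2 and 29.6 CPM in HET-labelled replicate 1, where WT replicate 1 had 4320 CPM. The seminal vesicle transcription factor gene Pax2 had 17.9, 3.77 and 0.0547 CPM in these libraries.

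**Figure D4:**
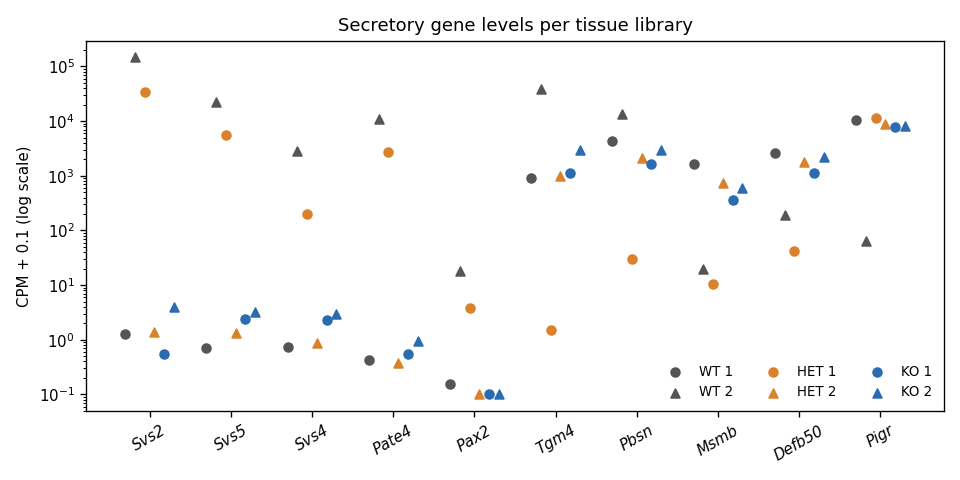
Counts-per-million plus 0.1 on a log axis for secretory and related genes in each of the 6 tissue libraries, with 1 point per library. WT replicate 2 and HET-labelled replicate 1 stand apart from the other 4 libraries in most of these genes.

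Type I interferon genes were placed higher in HET-labelled and KO-labelled than in WT tissue, with all 32 members above 0 and medians of 1.57 and 1.92 (camera adjusted p = 3.27e-16 and 2.81e-22, lost at adjusted p = 0.812 in both with an estimated correlation). Oasl2, an interferon-induced gene, differed by log2 1.78 in HET-labelled tissue (SE 1.29, edgeR adjusted p = 0.997, n = 2 against 2). Set against the mean of WT 1, HET 2, KO 1 and KO 2 (each of these against the other 3), the median of the list lay at -3.127 in WT replicate 2 and -0.703 in WT replicate 1, at 0.408 and -0.262 in HET-labelled replicates 1 and 2, and at 1.322 and -0.341 in KO-labelled replicates 1 and 2, so the medians above rest largely on WT replicate 2 and on 1 library of each other label. Without WT replicate 2, WT replicate 1 was the only WT library and showed no spread of its own. The list was still called there with the preset correlation in HET-labelled and KO-labelled tissue, which cannot separate genotype from single libraries. Unfolded protein response genes were placed lower in both (2.4e-09 and 6.66e-08, lost at adjusted p = 0.812 in both with an estimated correlation), with all 25 below 0, and lost the call without WT replicate 2 (camera adjusted p = 0.0568 and 0.7). Luminal progenitor (2.75e-07 and 6.66e-08), basal (2.8e-06 and 5.27e-09), NF-kappaB (6.32e-06 and 4.79e-05), squamous (0.0359 and 7.02e-04) and hypoxia genes (0.00209 and 0.0489) were placed higher in both, and fibroblast markers lower (2.76e-05 and 1.66e-09), and all of these calls were lost with an estimated correlation (adjusted p = 0.812 or 0.827). Without WT replicate 2, squamous genes turned lower in HET-labelled tissue and were not called in KO-labelled tissue (camera adjusted p = 0.82 and 0.0503), hypoxia genes were not called in HET-labelled and turned lower in KO-labelled tissue (0.788 and 0.104), and luminal progenitor genes were not called in KO-labelled tissue (0.102). Without HET-labelled replicate 2, the calls of squamous (camera adjusted p = 0.453), hypoxia (0.218) and fibroblast genes (0.11) were lost in HET-labelled tissue, and adipocyte markers, lower there in the full set, turned higher (0.281) and were not called without WT replicate 1 or 2 (0.0814 and 0.0712). HET-labelled tissue further had lower smooth muscle (9.93e-06) and adipocyte markers (0.0182) and higher leukocyte markers (1.73e-06), all lost at adjusted p = 0.812 with an estimated correlation. Without HET-labelled replicate 1, smooth muscle and leukocyte markers were not called (camera adjusted p = 0.175 and 0.573), and without WT replicate 2 smooth muscle was not called (0.165). KO-labelled tissue further had higher cell cycle (2.11e-05, 38 of 38 above 0), p53 target (1.2e-04), cholesterol (0.0421) and MAPK genes (0.0359) and lower mesenchymal genes (0.0248), all lost with an estimated correlation (adjusted p = 0.812 or 0.827). Cholesterol genes turned lower without WT replicate 2 (camera adjusted p = 0.66) and were not called without KO-labelled replicate 2 (0.0919), and cell cycle genes were not called without WT replicate 2 (0.289). Without KO-labelled replicate 1 cell cycle, cholesterol, MAPK, mesenchymal and hypoxia genes were not called (camera adjusted p = 0.0854, 0.0603, 0.0556, 0.0563 and 0.305), and without WT replicate 1 MAPK and mesenchymal genes were not (0.285 and 0.412).

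Between KO-labelled and HET-labelled tissue, cell cycle (camera adjusted p = 3.73e-05), p53 target (1.5e-08), MAPK (0.0248), smooth muscle (4.66e-06) and red blood cell genes (0.0414, 5 measured) were placed higher, and leukocyte (1.74e-06) and fibroblast markers (0.0233) lower, all lost with an estimated correlation (adjusted p = 0.812 or 0.827). Adipocyte markers were placed higher (0.0285, lost at adjusted p = 0.817 with an estimated correlation) although their median was -0.11, and turned lower without HET-labelled replicate 2 (camera adjusted p = 0.0518), where MAPK genes were not called (0.759). Without HET-labelled replicate 1 leukocyte markers turned higher (camera adjusted p = 0.252), red blood cell genes turned lower (0.376), and fibroblast markers, smooth muscle and cell cycle genes were not called (0.629, 0.446 and 0.987). Without KO-labelled replicate 2 red blood cell genes turned lower (camera adjusted p = 0.59) and adipocyte markers were not called (0.345), and without KO-labelled replicate 1 fibroblast, cell cycle and MAPK genes were not called (0.363, 0.305 and 0.0903). Neither fry nor the gene test called any list or any member in tissue. No gene of 16739 passed the edgeR test for HET-labelled against WT, KO-labelled against WT or KO-labelled against HET-labelled tissue. At unadjusted p < 0.05 there were 455, 322 and 97 genes where 837 would be expected by chance. DESeq2 called 19, 23 and 16. Brca1 differed by log2 -0.21 (0.18 by TPM), -0.28 and -0.08, and its sign turned without WT replicate 1 in the first (log2 0.03) and without KO-labelled replicate 2 in the others (log2 0.06 and 0.24). The receptor gene Nr3c1 differed by -0.19, -0.68 and -0.49, Pgr by -0.48, -1.61 and -1.13, and Esr1 by -0.28, -0.44 and -0.16, and for these genes and Brca1 edgeR adjusted p was 0.997 or higher with all 6 libraries. Leaving out WT replicate 2 and HET-labelled replicate 1, a choice made after seeing the data, left 1 library each of WT and HET-labelled tissue. Without WT replicate 1 alone, replicate 2 was the only WT library. Counts of called genes from these fits are listed only among the processing alternatives below. No conclusion on genotype is drawn from them, since a lone library shows no spread of its own.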

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

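In this part, the test on pseudogenes and the tests on secretory transcripts in both tissue libraries were chosen only after the result was seen.

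The response to DHT withdrawal differed between HET-labelled and WT organoids for 6 gene lists by camera on the difference itself. Hypoxia and glycolysis genes responded more negatively (adjusted p = 1.29e-10, 24 of 25 members below 0, adjusted p = 0.0876 with an estimated correlation), as did p53 targets (3.22e-06, 24 of 28 below 0, 0.109). Cell cycle genes responded more positively (3.22e-06, 35 of 38 above 0, 0.0998), as did squamous genes (5.17e-05, 18 of 19 above 0, 0.0487), homologous recombination genes (0.00141, 24 of 30 above 0, 0.246) and interferon genes (0.0126, 28 of 32 above 0, 0.665), which turned lower without WT minus DHT 2 (0.967) and without the 3 libraries that stood apart (0.747). The same 6 lists differed in the same directions between KO-labelled and WT organoids. These were cell cycle (adjusted p = 1.75e-09, 36 of 38 above 0, adjusted p = 0.0367 with an estimated correlation), hypoxia (1.75e-09, 24 of 25 below 0, 0.109), squamous (7.68e-06, 16 of 19 above 0, 0.0338), p53 (8.63e-06, 26 of 28 below 0, 0.122), interferon (0.00407, 24 of 32 above 0, 0.597) and homologous recombination genes (0.0324, 21 of 30 above 0, 0.424), which turned lower without the 3 libraries with the fewest reads (0.961). Both sets are measured against the same 6 WT libraries, so a shift in those libraries would enter both. Among 33 groupings of the genotype labels within each medium, the real one included, 16 gave as many genes at unadjusted p < 0.05 as the 433 for HET-labelled against WT, with 3204 the highest other. For KO-labelled against WT it was 16 of 33 (418, highest other 4906) and for KO-labelled against HET-labelled 23 of 33 (151, highest other 6292). Regroupings moved the labels separately in each medium, so differences between genotypes can enter them as a response difference. High counts there need no further structure of the samples, and these shares cannot show what chance alone would give. Chance is not excluded for the 433, 418 and 151 genes, which all lie under the 771 expected by chance.

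The first pattern is the set of 431 genes that differed between KO-labelled and WT organoids in the same direction in both media. DNA linked to the targeted locus as the source of most of them is argued against, as 3.48% (15 of 431, exact 95% interval 1.96 to 5.68) lay within 20 Mb of Brca1 against 3.47% of other genes. Kpna2, Axin2 and Krt16 are among these 15, and for each of them a variant linked to the locus stays open. Annotated pseudogenes were not most of them either, at 8.12% (35 of 431, exact 95% interval 5.72 to 11.1) against 8.26% of other genes. That share cannot decide whether reads shared between such copies and parent genes were the source of most. It leaves out parent genes, and the copies Ftl1-ps1 and Eno1b are annotated as protein-coding. Single genes such as Rpl34-ps1 and the ferritin pseudogenes could still owe their difference to a strain or line variant, and differing strain backgrounds of the lines were not tested and stay open. An effect of the genotype label is a hypothesis that these data leave open.

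The second pattern is the higher RNA of cell cycle genes in HET-labelled organoids than in both other genotypes. It does not rest on the 3 libraries with the fewest reads, since without them the list median kept at least 93.8% of its value in the 3 comparisons that hold any of them. WT minus DHT 2, HET minus DHT 3 and KO minus DHT 3 could share an unlabelled batch. Such a batch would hold every genotype label equally in the same medium, so leaving it out cannot test it as the source. Without these libraries the list median kept at least 91% of its value in both comparisons without DHT. With the mitochondrial read share as a covariate it kept at least 98.9% in 4 comparisons, while the call for HET-labelled against WT with DHT was lost with an estimated correlation (camera adjusted p = 0.0596). Differences in strain, passage or time since splitting between the lines were not tested, and each may raise cell cycle genes, so an effect of the genotype label remains a hypothesis.

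The third pattern is the secretory transcripts that were high in tissue WT replicate 2 and HET-labelled replicate 1. A candidate explanation is seminal vesicle tissue in the sample, since the median of the seminal vesicle list lay 5.402 log2 units above the other 4 libraries in WT replicate 2 and 2.913 above in HET-labelled replicate 1, with 9 of 11 members above in each (exact two-sided sign test p = 0.0654), led by Svs2 at 146000 and 33900 CPM. Of these members Tgm4 also belongs to the prostate secretory list. KO-labelled replicate 2 had 10 of 11 above the rest of these 4 libraries (median 1.419), but Svs2 at 3.93 CPM. A larger share of prostate secretory cells would raise the prostate secretory list. In HET-labelled replicate 1 that list was not raised, at -1.704 with 4 of 18 members above (exact two-sided sign test p = 0.0309). KO-labelled replicate 1 had 3 of 18 above (median -0.486). Genes of 1 library are not independent, so these sign tests do not measure spread between samples and cannot exclude the explanation. In WT replicate 2 the prostate secretory list lay at -1.107 with 8 of 18 members above (exact two-sided sign test p = 0.815), so the members went both ways and this explanation cannot be told apart there.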

How the results depend on the processing

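Alternatives named here as added (libraries left out in sets, the mitochondrial covariate, protein-coding genes) were chosen only after the result was seen. Counts of called genes are given for WT, HET-labelled and KO-labelled withdrawal and for pairs of genotypes. The cause was not tested for any changed count. Of 7891 alternative values for 480 calls of named genes, 6922 kept the call and its direction, 969 lost the call and none reversed, and of 9305 values for 535 named results not called, 23 gained a call. Of 1567 values for 130 called lists, 1234 kept the call, 322 lost it and 11 reversed, and of 3695 for 278 lists not called, 172 gained one. Omitting a library from a tissue pair leaves a lone sample, assumed to vary like the other groups. Counts of called genes from tissue fits with a lone sample are listed below for completeness. They allow no conclusion on genotype, since a lone sample shows no spread of its own.

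DESeq2 gave 396, 290 and 274 for withdrawal, 4, 5 and 1 for differences between responses (HET against WT, KO against WT, KO against HET), 967 (KO against WT) and 976 (KO against HET) with DHT, 1152 and 786 without, and 19, 23 and 16 in tissue. Length offsets gave 273 for KO against HET without DHT. The replicate block gave 167 for HET withdrawal and 1 for the HET against WT response difference. In the block check, 12 of 18 organoid and 4 of 6 tissue libraries correlated best with a library of their own number. Tissue correlations took only the mirrored values 0.11, 0.211 and 0.408 with either sign, so the 4 of 6 are not separate results. Same-number organoid pairs ranged from -0.519 to 0.69 (median 0.035, 17 of 45 over 0.1). Minus DHT WT 3 stood at -0.507 and -0.519 with HET 3 and KO 3, so the numbers do not pair the samples across all groups. Between HET and KO without DHT, however, pairs numbered 1, 2 and 3 correlated at 0.614, 0.231 and 0.69. Unlike numbers there gave -0.633 to 0.107, so these libraries share a structure that follows the number. WT libraries without DHT shared in it across numbers. WT 3 stood at 0.355 and 0.444 with HET 1 and KO 1, and WT 2 at 0.447 and 0.481 with HET 3 and KO 3. WT 1 stood at -0.061 and -0.081 with HET 1 and KO 1. The structure can therefore also enter the comparisons with WT without DHT. Fits restricted to the groups compared gave 94, 0 and 12 for withdrawal, 1234 for KO against HET with DHT, and 389, 201 and 27 without DHT for HET against WT, KO against WT and KO against HET. With no low-count filter tissue gave 2 for HET against WT and 1 for KO against WT.

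Among added alternatives, leaving out the 3 libraries with the fewest reads gave 332 for WT withdrawal and 1 for the KO against WT response difference. Leaving out the 3 that stood apart gave 254 for KO against HET without DHT. The mitochondrial read share as a covariate gave 715, 293 and 452 for withdrawal, 2 and 3 for the HET and KO response differences against WT, 2722, 1374 and 1579 with DHT and 2275, 1656 and 1312 without. Tissue without WT 2 and HET 1 gave 27, 82 and 60. An estimated correlation took the 130 list calls to 34. The stricter filter moved the correlations of withdrawal responses to 0.272, 0.216 and 0.446. Brca1 in HET over WT tissue was 0.176 by TPM (log2), against -0.204 by CPM.

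Leaving out 1 library gave 116 to 196 genes for WT withdrawal (132 without WT plus DHT 2, 116 without plus DHT 3, 117 without minus DHT 2). HET withdrawal gave 43 to 81 (HET plus DHT 1: 55, 2: 43, minus DHT 1: 54, 2: 58) and KO withdrawal 42 to 59 (KO plus DHT 1: 47, 2: 42, 3: 49, minus DHT 2: 51, 3: 54). With DHT, HET against WT gave 707 to 838 (HET 2: 732, HET 3: 707, WT 3: 713), KO against WT 395 to 562 (KO 2: 408, KO 3: 406, WT 3: 395) and KO against HET 246 to 351 (HET 1: 299, 2: 287, 3: 351, KO 1: 246, 2: 327, 3: 267). Without DHT these were 808 to 1474, 412 to 732 (KO 2: 430, WT 1: 412, 2: 439, 3: 470) and 226 to 366 (HET 2: 229, KO 2: 226). Response differences gave 0 to 0. Tissue gave 0 to 84 for HET against WT (84 without WT 1) and 0 to 0 for the other pairs. List calls ranged from 123 to 138.

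The 11 reversed list directions had the camera adjusted p that follow, with the range over single libraries left out. In response differences they were 0.967 without WT minus DHT 2 and 0.747 without the libraries that stood apart for interferon, HET against WT (6.6e-07 to 0.967), and 0.961 without the fewest-read libraries for homologous recombination, KO against WT. In tissue, HET against WT reversed for squamous genes (0.82 without WT 2, range 0.000181 to 0.82) and adipocyte markers (0.281 without HET 2, range 8.68e-10 to 0.281). KO against WT reversed for cholesterol (0.66 without WT 2, range 0.00597 to 0.66) and hypoxia genes (0.104 without WT 2, range 0.000136 to 0.305). KO against HET reversed for leukocyte markers (0.252 without HET 1, range 1.58e-09 to 0.252), red blood cell genes (0.376 without HET 1 and 0.59 without KO 2, range 9.97e-06 to 0.59) and adipocyte markers (0.0518 without HET 2, range 5.51e-19 to 0.345).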

Other observations

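In this part, the genes Itga9, Ccl28 and Rgs2 were chosen only after the result was seen.

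Gpd1l, Spry4 and Clu differed by genotype label in both media. The glycerol phosphate dehydrogenase-like gene Gpd1l was higher than in WT in HET-labelled organoids (log2 1.19 with DHT, SE 0.0764, and 1.11 without, SE 0.0759) and in KO-labelled organoids (log2 0.80, SE 0.0759, and 0.74, SE 0.0755). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, was higher by log2 1.04 and 1.05 in HET-labelled and by 0.74 and 0.86 in KO-labelled organoids. Clu, which encodes the chaperone clusterin, was higher by log2 1.01 and 0.59 in HET-labelled and by 0.94 and 0.54 in KO-labelled organoids. Each of these passed the edgeR test with 3 libraries per group.

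Itga9, Ccl28 and Rgs2 fell on DHT withdrawal in all 3 genotype labels. The integrin gene Itga9 fell by log2 -2.45 (SE 0.341, edgeR adjusted p = 0.000883) in WT, -2.35 in HET-labelled and -2.32 in KO-labelled organoids. The chemokine gene Ccl28 fell by log2 -2.23, -1.74 and -2.97, and Rgs2, a regulator of G protein signalling, by -1.28, -1.25 and -1.25.

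Genes that differed between organoids in both media were followed in tissue. For those higher in HET-labelled organoids, camera with an estimated correlation gave p = 0.476 (0.0451 with the preset correlation), with 263 of 439 lying higher in HET-labelled than in WT tissue. For those lower camera gave p = 0.495 with an estimated correlation (0.0177 with the preset correlation, towards higher RNA and so opposite to organoids), with 121 of 304 lying lower. For those higher in KO-labelled organoids camera with an estimated correlation gave p = 0.709 (0.537 with the preset correlation, 131 of 262 lying higher) and for those lower p = 0.278 (8.9e-04 with the preset correlation, again opposite to organoids, 54 of 149 lying lower). A shared genotype effect in organoids and tissue is therefore left open, as the 3 p-values under 0.05 with the preset correlation were lost with an estimated one.

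For each comparison of 3 against 3 organoid libraries there are 10 splits, too few for a share under 0.05. For withdrawal, 1 of 10 splits, the real split, gave as many genes as it did, with 200, 109 and 86 genes for WT, HET-labelled and KO-labelled organoids and at most 0 in the others. With DHT it was 1 of 10 for each pair (1153 for HET-labelled against WT with highest other 1, 635 for KO-labelled against WT with 0, 544 for KO-labelled against HET-labelled with 0). Without DHT it was 1 of 10 for HET-labelled against WT (1203, highest other 0) and KO-labelled against WT (742, highest other 1). At unadjusted p < 0.05 in edgeR, however, another split exceeded the real one in both, with 4898 against 2908 and 4721 against 2285 genes. The same held for withdrawal in HET-labelled (3279 against 1293) and KO-labelled organoids (1646 against 1085). It did not hold for WT withdrawal or for any pair with DHT. For KO-labelled against HET-labelled organoids without DHT, 3 of 10 splits called as many genes as the real one, with 448 for the real split and 5376 for the highest other. That split set KO minus DHT 1 and HET minus DHT 1 and 2, with 10.01%, 9.43% and 4.54% mitochondrial reads, against KO minus DHT 2 and 3 and HET minus DHT 3, with 4.17%, 2.61% and 2.42%. It points to a structure among these 6 libraries, whose mitochondrial read share fell with the replicate number. WT minus DHT 2 and 3 also correlated with some of these libraries, as given above. The splits with 5376 and 3472 genes kept the HET and KO libraries of number 1 together, and those of number 3. Splits that parted the HET and KO libraries of every number gave 0 genes, apart from the real one. These are fewer than 10, so they cannot reach a share under 0.05 either. With the replicate number as a block 530 genes were called, and with the mitochondrial read share as a covariate 1312.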
